A study of Mus musculus with 9 samples.

How the data were processed

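Single-cell TCR libraries were made from lymph node cells of WT and 5xFAD mice with a 10x Genomics immune profiling kit, after cells were tagged with 4 hashtag antibodies and samples of above 87% viability were kept, per the labels' protocols. Each of 9 samples had 1 table with a row per assembled contig. Cell Ranger 6.0.1, Seurat 4.1.0 and the mm10 build are named in the submitters' processing notes, with no role given. V, D and J genes were called with IgBLAST against germline alleles, per the file headers and the column set.

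The deposited counts are the UMI count and the read count of each contig, whole numbers without normalization, per the file headers. The deposited fraction is the V identity, matching bases over aligned bases, per the file headers. Other deposited values are lengths in nucleotides of the junction and of the added bases, per the file headers. The 6 main libraries listed productive contigs only, whereas the CD4-titled and mixed libraries also held 37, 39 and 32 nonproductive contigs. These 3 libraries were also called against another allele set than the 6 main ones. TRAV genes were therefore summed by subgroup number, which also joins near-identical duplicated copies. The values of these libraries were set beside the others with counting or exact intervals, and without a p-value.

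A cell was a barcode with exactly 1 productive TRB chain and 1 or 2 productive TRA chains, the TRA chain with more UMIs being kept. Barcodes with 2 or more TRB or 3 or more TRA chains were set aside as possible doublets. These made up 1.45% to 5.58% of barcodes per library. No other doublet caller was run. A clonotype was a distinct combination of TRBV, TRBJ and TRB junction nucleotides with TRAV subgroup, TRAJ and TRA junction nucleotides. Clonotypes per feature and library were counted for TRBV, TRBJ and TRAJ genes and TRAV subgroups, so that a repeated clone counted as 1. Features with under 10 clonotypes in the 6 main libraries were left out, which kept 94 of 96.

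Usage was tested with edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood fit on node type and genotype and the number of clonotypes per library as offset. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. As each node had 1 library per genotype, the spread was estimated from how genotype differences vary over 3 node types, and p-values do not measure the spread between animals. The fit was tested on simulated counts for 94 features with 20 changed in each of 20 draws: in the genotype comparison 42% of features changed 1.5-fold and 82% of those changed 2-fold were recovered, with 5.6% and 3.5% of calls false. The simulation used a dispersion of 0.01 and the same genotype change in each node. Genotype differences in the data varied over nodes, so these rates do not give the power of the fit on the data. Within a node, log2 ratios of shares used a pseudocount of 0.5 and 95% counting intervals. Shares had exact Clopper-Pearson 95% intervals, and a count of 0 was given an upper limit of 3 counts. Single values per library were compared between genotypes with an exact sign-flip permutation test over 3 node types, two-sided, which cannot go below 0.25.

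TRA and TRB V regions, from the start of the mature V region to the base before the junction, were searched as exact matches in the spliced V transcripts of the GENCODE annotation of GRCm38. TRAV subgroups were called informative where under 2% of at least 30 chains in the 5xFAD libraries matched, a choice that sets the 5xFAD value near 0, so shares over all TRA chains are given too. This search was added after the data were seen. Gene positions came from the same annotation.

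Features were named by a rule fixed before the data were examined. For genotype these were all past the threshold, then those with the largest fitted change among features with a mean of at least 20 clonotypes and the same direction in 3 node types, up to 20, with direction read from the log2 ratio with pseudocount, by which TRBV17 was named though its raw share in dCLN was marginally higher in 5xFAD. For node contrasts these were all past the threshold, then the 5 largest with the same direction in both genotypes and a mean of at least 20 clonotypes. For the CD4-titled sample these were the 10 largest mean ratios with the same direction against both dCLN libraries and a mean of at least 20 clonotypes. The lists (SJL block, TRBJ groups, TRAJ numbers, CD4- and CD8-skewed subgroups, junction measures, iNKT and MAIT chains) were fixed at the same time. The 5 genes named within nodes outside that rule were chosen after their values were seen.

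Alternatives covered the counted unit, the test (DESeq2 1.42.0), the scaling, the filter, TRAV naming, ambiguous calls, barcodes with extra chains, a minimum of 2 UMIs and leaving out each library. DESeq2 was first run with a mean dispersion trend. Its default trend was added after that run had called 0 features, and both are given. A planned comparison of the genotype difference between the dCLN preparations was void, as the CD4-titled libraries hold the same cells. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 did the remaining work. Depth limits precision: a feature at 20 clonotypes per library carries a wide counting interval, and the smallest main library held 1086 clonotypes.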

Results

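T-cell receptor (TCR) chains were sequenced from single cells of deep cervical (dCLN), superficial cervical (sCLN) and inguinal (iLN) lymph nodes of wild-type (WT) mice and of 5xFAD mice, a transgenic line carrying familial Alzheimer's disease mutations. The deep cervical nodes drain the brain and its meninges, the superficial ones the face and scalp, and the inguinal ones the lower body. Female mice of 10 to 11 months were used. Each node and genotype gave 1 library, so 6 libraries formed the main comparison. A further pair of dCLN libraries carried CD4 in their titles, labelled WT and 5xFAD, and 1 library mixed 3 node types and both genotypes. The labels do not say how many animals stood behind a library, or whether the nodes came from the same animals. Differences between libraries therefore have no replicate check within a node, and intervals on single libraries cover counting error only.

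The libraries held 3458 to 13137 contigs each. Cells used, which had 1 productive TRB chain with 1 or 2 productive TRA chains, numbered 1227 in dCLN WT, 2742 in dCLN 5xFAD, 1123 in sCLN WT, 2326 in sCLN 5xFAD, 1688 in iLN WT and 1151 in iLN 5xFAD. These gave 1173, 2726, 1086, 2284, 1662 and 1142 distinct clonotypes. Pairing of TRA with TRB was lowest in iLN 5xFAD, at 43.1% of barcodes (exact Clopper-Pearson 95% interval 41.2 to 44.9), and highest of the 6 main libraries in sCLN 5xFAD, at 66.6% (65.1 to 68.2). The median contig measured 524 nucleotides in iLN 5xFAD and 540 in sCLN 5xFAD. The CD4-titled libraries held 4930 and 4991 cells used, and the mixed library 2873. No chain of the TRG, TRD or immunoglobulin loci was listed in any library (0 contigs), so gamma-delta T cells and B cells could not be counted.

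The CD4-titled libraries labelled WT and 5xFAD held the same cells. They shared 6829 cell barcodes, out of 6905 and 6915, and 12709 combinations of barcode and junction sequence. Among the other 35 library pairs the highest number of shared barcodes was 47, with 0 shared combinations of barcode and junction. Across 94 V and J features the median absolute log2 ratio between the CD4-titled libraries was 0.02, against 0.25 between the dCLN libraries of the 2 genotypes. They were counted as 1 sample, and no genotype comparison was drawn from them.

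The question of the main comparison was whether T cells of 5xFAD mice use other receptor genes than those of WT mice. TRAV4 and TRAV3, both subgroups of V genes in the TRA locus, were lower in 5xFAD. TRAV4, known for its use in CD4 T cells, made up 7.39% ± 0.93 of clonotypes in WT and 5.09% ± 1.13 in 5xFAD (SD, n = 3 node types each), a log2 fold change of -0.55 with a standard error of 0.16 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.034). TRAV3 made up 3.33% ± 0.56 in WT and 1.79% ± 0.20 in 5xFAD, a log2 fold change of -0.86 with a standard error of 0.25 (edgeR adjusted p = 0.034). Both were lower in 5xFAD in 3 of 3 node types. No other feature of the 94 tested passed the threshold, and 13 had an unadjusted p under 0.05. The V genes of the TRA locus lie on chromosome 14 from 52427928 to 53977678 in GRCm38, and its J genes from 54155005 to 54218842. Calls that named more than 1 TRAV gene made up 22.2%, 20.4% and 21.5% of TRA calls in dCLN, sCLN and iLN WT, against 5.49%, 6.13% and 5.45% in 5xFAD. Leaving out any of the 6 libraries left 0 features past the threshold, with TRAV4 at -0.64 without either dCLN library, -0.70 without either iLN library and -0.32 without either sCLN library, and TRAV3 between -0.996 and -0.66; DESeq2 (-0.56 and -0.88), UMIs in place of clonotypes, a minimum of 2 UMIs per chain and all chains paired or not also gave 0. Among non-reference TRA chains alone TRAV4 stood at -0.14 (standard error 0.22) and TRAV3 at -0.23 (0.34), TRAV3 turned to 0.15 with ambiguous gene calls left out, and 24 features passed with TRAV counted by gene.

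The remaining features named by size did not pass the test. Among J genes of the TRA locus, TRAJ21 had a log2 fold change of -0.84 (edgeR adjusted p = 0.068), TRAJ6 of -0.57, TRAJ22 of -0.56, TRAJ37 of -0.51 and TRAJ33 of -0.46. TRAJ7 and TRAJ12 had values of -0.30 and -0.23. The J genes with higher values in 5xFAD were TRAJ32 at 0.47, TRAJ39 at 0.37, TRAJ40 at 0.25 and TRAJ31 at 0.20. Among TRAV subgroups, TRAV12 had a value of -0.39, TRAV8 of 0.39 and TRAV13 of 0.28. On the TRB side, TRBJ1-1 had a value of -0.29, TRBV17 of -0.28, TRBV20 of -0.22 and TRBV1 of 0.27. For TRBV17 the dCLN shares were level, at 1.53% in WT and 1.54% in 5xFAD. The adjusted p of these features, TRAJ21 included, ran from 0.068 to 0.74. TRAJ21 passed with cells counted and with TRA features alone, and TRAV12 with ambiguous calls left out. TRAJ35, which fell under the minimum of 10 clonotypes with 3 in each WT library and 0 in each 5xFAD library, passed without that minimum.

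The gene lists fixed before the data were examined gave 1 call. Of the subgroups known as skewed to CD4 T cells (TRAV4 and TRAV14) or to CD8 T cells (TRAV9), all 3 had negative values and 1, TRAV4, passed, also when adjusted over the list alone. TRAV14 made up 9.22% ± 0.86 of WT clonotypes and 7.89% ± 1.28 of 5xFAD clonotypes (SD, n = 3), and TRAV9 made up 1.505% ± 0.81 and 1.15% ± 0.86. Without iLN the TRAV9 difference turned to 0.49 percentage points and that of TRAV14 went from -1.33 to -0.53, while without sCLN that of TRAV14 was -2.33 and that of TRAV4 went from -2.30 to -1.35. Of 14 TRAJ genes numbered 40 or above, which lie at the end of the J cluster next to the V genes, 13 had positive values, from -0.09 to 0.37 on the log2 scale over the list, and 0 passed the test, adjusted over the list alone or over all features. Their summed share was 32.1% ± 1.12 in WT and 35.7% ± 1.05 in 5xFAD (SD, n = 3), higher in 3 of 3 node types (exact sign-flip permutation test, two-sided p = 0.25, the smallest this design allows). Of the 9 TRBV genes that the SJL mouse strain lacks, 7 had negative and 2 positive values, with 0 past the threshold, adjusted over the list alone or over all features. This block made up 44.5% ± 2.70 of WT and 42.0% ± 3.34 of 5xFAD clonotypes (SD, n = 3), higher in 5xFAD in 1 of 3 node types (exact two-sided p = 0.75), and without sCLN the mean difference turned to 0.0456 percentage points. The 6 TRBJ2 genes had 4 positive and 2 negative values and the 6 TRBJ1 genes 3 of each, with 0 past the threshold in either group, also adjusted over the list alone. The TRBJ2 share was 65.8% ± 2.54 in WT and 68.0% ± 0.83 in 5xFAD (SD, n = 3; exact two-sided p = 0.50), a difference of 2.25 percentage points that was 1.12 without iLN and 3.94 without sCLN.

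TRA V regions themselves differed in sequence between the WT and 5xFAD libraries of the 3 nodes. Over all TRA chains, 54.7% in dCLN WT (exact 95% interval 52.2 to 57.2), 54.0% in sCLN WT (51.4 to 56.5) and 55.2% in iLN WT (53.0 to 57.3) matched the GRCm38 reference exactly up to the junction, against 13.1% (12.02 to 14.2), 12.9% (11.7 to 14.1) and 14.99% (13.3 to 16.9) in the same nodes of 5xFAD. The CD4-titled libraries stood at 35.0% and 34.6%. The mixed library, titled as holding both genotypes, stood at 95.1%, above each of the 6, a share that no mix of these 6 would give. In 10 TRAV subgroups chosen because under 2% of their 5xFAD chains matched, 44.5% of dCLN WT chains (exact 95% interval 40.9 to 48.2), 45.6% of sCLN WT chains (41.9 to 49.4) and 48.7% of iLN WT chains (45.6 to 51.8) matched. The low 5xFAD share in these subgroups, 1 chain in sCLN and 0 in dCLN and iLN, follows from that choice. TRB V regions matched the reference in 94.6% to 96.0% of chains in the 6 main libraries, and in 99.9% in each of the other 3. Every TRAV and TRAJ value above was therefore measured between libraries whose TRA germline sequences differed.

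**Figure D1:**
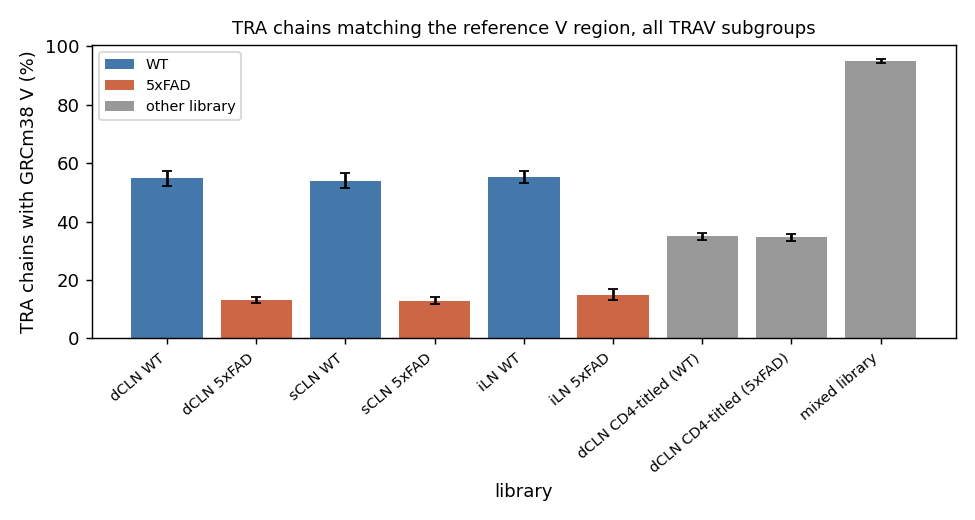
Share of all TRA chains whose V region matched GRCm38 exactly, in percent (vertical axis), in each library (horizontal axis), with exact 95% intervals as error bars. The WT libraries sat between 54.0% and 55.2%, the 5xFAD libraries between 12.9% and 14.99%, and the CD4-titled libraries at 35.0% and 34.6%.

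Within single nodes, several V genes differed between the genotypes in opposite directions. TRBV2 made up 3.31% of iLN WT and 0.53% of iLN 5xFAD clonotypes, a log2 ratio of -2.55 (95% counting interval -3.72 to -1.39). In sCLN it made up 1.29% in WT and 3.11% in 5xFAD, a log2 ratio of 1.23 (0.42 to 2.04). TRAV9 had ratios of -2.63 in iLN and 1.25 in sCLN, and TRBV19 of -0.88 and 1.23. TRBV15 and TRBV13-1 went the other way, with ratios of 1.08 and 0.39 in iLN and of -0.94 and -0.60 in sCLN. In dCLN the intervals of all 5 genes included 0. Of the 94 features, the counting interval lay above 0 for 3 in dCLN, 7 in sCLN and 8 in iLN, and below 0 for 8, 8 and 9. TRBV2 lies on chromosome 6 from 41047340 to 41047995 and TRBV19 from 41178375 to 41179048 in GRCm38. With 1 library per group these ratios compare libraries, and no p-value was computed.

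**Figure D2:**
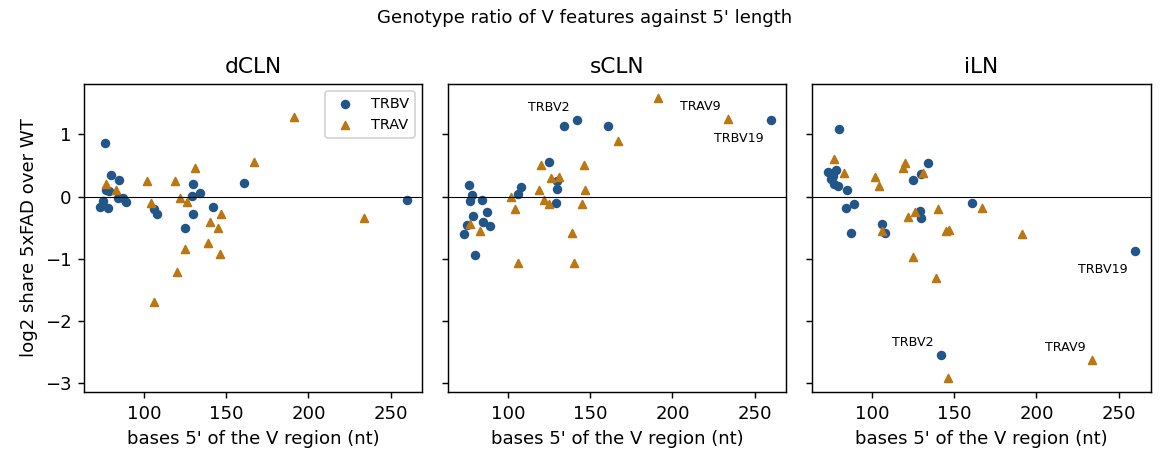
Log2 ratio of clonotype shares, 5xFAD over WT (vertical axis), against the median number of contig bases upstream of the V region in the mixed library, in nucleotides (horizontal axis), for 21 TRBV genes (circles) and 19 TRAV subgroups (triangles) in each node. Long upstream parts went with higher ratios in sCLN (Spearman rho 0.62 across genes, which are not independent replicates) and lower ratios in iLN (-0.58), with -0.21 in dCLN, where no gene is named in the plot.

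Between nodes no feature passed the test. In each of the contrasts dCLN against sCLN, dCLN against iLN and sCLN against iLN, 0 of 94 features passed an adjusted p of 0.05 with edgeR (2, 3 and 2 at an unadjusted p under 0.05). DESeq2 also gave 0, with 0 at an unadjusted p under 0.05. It had 0 at that level in the genotype comparison too, so its 0 calls add little evidence that the nodes are alike. TRBJ1-2, a J gene on chromosome 6 from 41534001 to 41534048, had the lowest p in both contrasts with iLN. It made up 7.10% of iLN WT and 6.74% of iLN 5xFAD clonotypes, 4.35% and 4.44% in dCLN, and 3.68% and 4.86% in sCLN. Its log2 fold change was -0.67 for dCLN minus iLN (edgeR adjusted p = 0.12) and -0.67 for sCLN minus iLN (adjusted p = 0.15). For dCLN minus sCLN the named features were TRAJ53 at -0.56, TRAJ9 at 0.45, TRBJ1-3 at -0.42, TRAJ58 at 0.40 and TRBV17 at -0.38. For dCLN minus iLN they were also TRBV3 at 0.47, TRAJ7 at -0.46, TRAJ30 at 0.43 and TRBV26 at 0.39. For sCLN minus iLN they were also TRAJ48 at 0.50, TRAJ9 at -0.47, TRAV10 at 0.43 and TRAJ30 at 0.41. Without sCLN WT 1 feature passed for dCLN against sCLN and 1 for sCLN against iLN, and without iLN WT 2 passed for sCLN against iLN.

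The CD4-titled sample, whose TRA reference share lay between those of dCLN WT and dCLN 5xFAD, differed from both in many V genes. TRAV9 made up 7.90% of its clonotypes, against 1.28% in dCLN WT and 1.03% in dCLN 5xFAD, a mean log2 ratio of 2.75. TRBV2 made up 8.02% against 1.71% and 1.54%, and TRBV19 7.44% against 2.73% and 2.64%. TRAV17 stood at 0.99% against 0.09% and 0.29%. TRAJ35 stood at 0.85% against 0.26% in WT, and 0 of 2726 clonotypes in 5xFAD, which allows up to 0.11%. Lower in the CD4-titled sample were TRBV29, at 1.29% against 4.77% and 4.55%, TRBV12-1, with a mean log2 ratio of -1.30, TRAV1 with -1.12, TRAV8 with -0.91 and TRBV17 with -0.90. Of 90 features, 8 were higher and 15 lower than in both dCLN libraries by intervals that excluded 0. The CD4-titled and mixed libraries were called against another allele set, and summing TRAV genes by subgroup does not cover TRAJ or TRBV calls. TRAJ24, too rare to be among the 90, had 0 and 1 clonotypes in the CD4-titled libraries and 1 in the mixed library. It had 8 to 28 in the main libraries. How far gene calling shaped the TRAJ and TRBV differences was not tested. In the mixed library, which has no CD4 in its title, TRAV9 made up 7.31%, TRBV2 5.37% and TRBV19 6.57%. TRAV9 is known for its use in CD8 T cells. Across 40 V features, which are not independent replicates, the log2 ratio of the 6 main libraries over the mixed library had a Spearman rho of -0.50 with the length upstream of the V region. The CD4-titled and mixed libraries also held more long contigs: 16.05% and 14.7% of their contigs exceeded 600 nucleotides, against 3.84% in dCLN WT and 4.09% in dCLN 5xFAD.

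Repeated clonotypes were more frequent in WT than in 5xFAD nodes. After thinning each library to 1123 cells (mean of 200 draws), 5.48% ± 3.08 of WT and 1.26% ± 0.70 of 5xFAD cells (SD, n = 3 node types) belonged to clones of 2 or more cells. The share was higher in WT in 3 of 3 node types, at 7.91% against 0.47% in dCLN, 6.50% against 1.80% in sCLN and 2.02% against 1.52% in iLN (exact sign-flip permutation test, two-sided p = 0.25, the smallest this design allows; 0.75 after Benjamini-Hochberg adjustment over 12 such comparisons). Without dCLN the mean difference went from -4.21 to -2.60 percentage points. Unthinned, dCLN WT held 8.64% (exact 95% interval 7.13 to 10.4) and dCLN 5xFAD 1.17% (0.80 to 1.64). The clones were small. The largest held 3 cells in each WT library and 2 cells in each 5xFAD library. Clones of 2 or more cells numbered 52 in dCLN WT, 36 in sCLN WT and 25 in iLN WT, of which 2, 1 and 1 held 3 or more. They numbered 16, 42 and 9 in the same nodes of 5xFAD, with 0 of 3 or more. In the larger CD4-titled library labelled WT, 23 of 95 such clones held 3 or more. In dCLN WT the 2 largest used TRBV26, with the TRB junctions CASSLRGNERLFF and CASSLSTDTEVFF, and in sCLN WT the largest used TRBV29 with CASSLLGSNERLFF. The CD4-titled sample held a TRBV5 clone with the junction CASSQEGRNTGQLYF of 11 cells in the library labelled WT, or 0.22% of its cells (exact 95% interval 0.11 to 0.40).

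**Figure D3:**
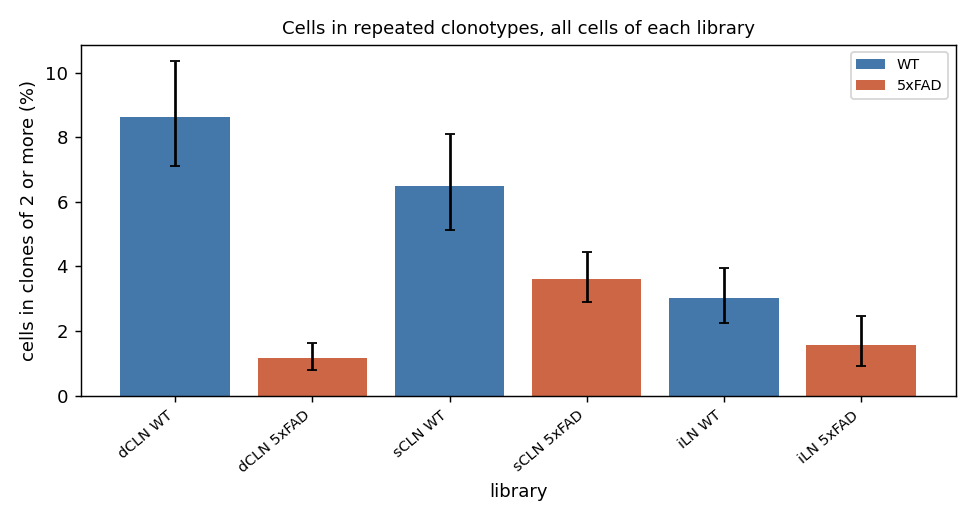
Cells in clones of 2 or more cells, in percent of all cells used and before thinning (vertical axis), in the 6 main libraries (horizontal axis), with exact 95% intervals as error bars. WT exceeded 5xFAD in each node, with 8.64% against 1.17% in dCLN.

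Clonotypes defined by the nucleotides of both chains were shared between nodes of the same genotype, and none were seen in libraries of different genotype. The 3 pairs of WT nodes shared 13 clonotypes, or 2.59 per 1000000 clonotype pairs compared (Poisson 95% interval 1.38 to 4.42), and the 3 pairs of 5xFAD nodes shared 2, or 0.17 per 1000000 (0.02 to 0.60). In 5xFAD, dCLN and iLN shared 1, sCLN and iLN shared 1, and dCLN and sCLN shared 0, so that without iLN 5xFAD the count was 0. The pair sCLN WT and iLN WT shared 8, so that the WT rate was 4.43 without dCLN WT, 2.36 without iLN WT and 1.03 without sCLN WT, where 2 shared clonotypes remained. Over the 9 pairs of libraries of different genotype 0 clonotypes were shared, which allows up to 0.12 per 1000000. The WT rate goes with WT nodes having come from shared animals, which the labels leave open. For 5xFAD the interval overlaps that between genotypes (Poisson 95% interval 0 to 0.15), so the 2 shared clonotypes cannot tell. If nodes came from shared animals, the 3 node types would be repeated samples of the same animals, not independent replicates. By amino acid junctions of both chains, 16 were shared within and 2 between genotypes, and with the TRB chain alone 27 and 21. Per 1000000 pairs, TRB alone gave 1.60 within genotypes. Between genotypes it gave 0.40 for the same node and 1.09 for different nodes. The sCLN WT clone of 3 cells with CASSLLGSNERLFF was also seen in 2 iLN WT cells.

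Invariant natural killer T (iNKT) chains were found in the WT nodes and not in the 5xFAD nodes. The chain, TRAV11 joined to TRAJ18 with a junction of 15 amino acids, was carried by 3 cells in dCLN WT, 6 in sCLN WT and 5 in iLN WT. All 14 had the canonical junction sequence and a usual TRB partner. In 5xFAD it was found in 0 of 6219 cells, which allows a share of up to 0.048%. The WT share was 0.36% ± 0.15 (SD, n = 3; exact sign-flip permutation test, two-sided p = 0.25, the smallest this design allows). The mixed library held 3 such cells and the CD4-titled libraries 0. The chain of mucosal-associated invariant T (MAIT) cells, TRAV1 joined to TRAJ33 with a junction as long as the canonical one, was carried by 13 of 4038 WT and 9 of 6219 5xFAD cells, or 0.33% ± 0.09 and 0.18% ± 0.14 (SD, n = 3; exact two-sided p = 0.50). Of these, 11 and 6 had the canonical junction and 7 and 7 a usual TRB partner. The mean difference was -0.15 percentage points, -0.080 without dCLN, -0.094 without sCLN and -0.28 without iLN.

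Junction length and hydrophobicity were close in both genotypes. The mean TRB junction measured 13.9 amino acids in WT and 13.9 in 5xFAD, a difference of 0.02 ± 0.09 (SD over 3 node types, 5xFAD minus WT; exact sign-flip permutation two-sided p = 0.75) that turned to -0.0191 without sCLN. The mean TRA junction measured 13.5 amino acids in each genotype, a difference of 0.053 ± 0.076 (exact two-sided p = 0.50) that ran from 0.031 to 0.097 without each node type. A hydrophobic residue at both junction positions 6 and 7 of TRB was found in 0.87% ± 0.29 of WT and 0.74% ± 0.08 of 5xFAD clonotypes (SD, n = 3; exact two-sided p = 0.75), and without iLN the difference turned to 0.0585 percentage points.

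The mixed library could not be divided by node or genotype and entered no test between groups; its contigs gave the upstream lengths, and its shares were set beside those of the others. Its clonotypes carried TRAV14 in 10.9%, TRAV9 in 7.31% and TRAV4 in 6.39%, and TRBJ2 genes in 62.3%. Cells in clones of 2 or more made up 2.54% (exact 95% interval 2.00 to 3.18), and its largest clone held 4 cells with TRBV13-2 and the junction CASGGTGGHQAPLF.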

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

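Of the tests below, those of contig length, of other splits and of upstream length over all V genes, and the fit on non-reference TRA chains, were chosen after the result was seen; the others were fixed before their value was seen.

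The lower TRAV4 and TRAV3 usage of the 5xFAD libraries stood beside a different TRA germline, with 54.7%, 54.0% and 55.2% of all TRA chains matching the reference in dCLN, sCLN and iLN WT against 13.1%, 12.9% and 14.99% in 5xFAD. A shortage of long contigs in 5xFAD is argued against for TRAV4 by sCLN, where 5xFAD contigs were longer. There TRAV3 with TRAV4 still had a log2 ratio of -0.92 (95% interval -1.26 to -0.58), and TRAV4 alone of -1.07 (-1.49 to -0.66). TRAV3 alone had -0.59 (-1.23 to 0.05) in sCLN and -1.30 in iLN, so contig length stays open for TRAV3. Haplotype stays open. Among non-reference chains alone TRAV4 went from -0.55 (standard error 0.16) to -0.14 (0.22) and TRAV3 from -0.86 (0.25) to -0.23 (0.34), which goes with it. In dCLN, sCLN and iLN WT, 58.5%, 56.9% and 65.0% of TRAV4 chains matched the reference. These are the chains that the non-reference fit leaves out, so their share is no separate support. Over the 10 informative subgroups, TRAV4 included, 44.5%, 45.6% and 48.7% matched. TRAV14 was also above these, and no difference was tested. The odds ratio of TRAV3 or TRAV4 between WT chains with and without a TRAJ allele absent from 5xFAD, at 1.34 (0.77 to 2.32), was too wide to decide. For the same TRAJ genes, WT chains with the other allele carried TRAV3 or TRAV4 in 11.1% (7.39 to 15.9), against 6.98% (5.28 to 9.01) in 5xFAD. This leans the other way, though the intervals overlap. An effect of the transgene also stays open, since the fit on non-reference chains, which compares the genotypes within a chain class, was imprecise. Only 10 splits of the 6 libraries exist, too few for a share under 0.05: 1 split, the real one, gave 2 calls, and the highest other gave 0. Some of the others put both libraries of a node on the same side, unlike the real split, which leaves still fewer comparable ones.

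The genotype ratios of 5 V genes lay on opposite sides of 0 in iLN and sCLN, a difference that was not tested gene by gene. The distance between the 2 nodes on the log2 scale was 3.88 for TRAV9, 3.78 for TRBV2, 2.11 for TRBV19, 2.03 for TRBV15 and 0.99 for TRBV13-1. A TRA haplotype is argued against for the TRBV genes only, since they lie on another chromosome. Over the 21 TRBV genes the difference in Spearman rho with upstream length between sCLN and iLN was 1.21 (bootstrap 95% interval 0.69 to 1.57). These include TRBV2, TRBV19, TRBV15 and TRBV13-1, which were picked for their opposite ratios, so this value is no separate support. For TRAV9 a TRA haplotype stays open. A candidate explanation is loss of chains with long upstream parts where contigs were shorter. Over 40 V features the difference in rho between sCLN and iLN was 1.19 (0.80 to 1.48), though genes are not independent replicates. The 40 features include the 5 genes, and contig length includes the upstream part. A usage difference in these genes would also shorten contigs, so this value cannot tell the explanations apart. A biological difference between nodes remains untested.

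Cell pairs within WT clones did not have near-identical barcodes: 0 of 121 pairs differed at 2 or fewer bases (upper 95% limit 3.00%). This argues against barcode errors of that size, and no others, as the source of the excess of repeated clonotypes in WT. Free RNA caught in another droplet was tested only for droplets left with few UMIs. Pairs in which the smaller cell had under 0.2 of the UMIs of the larger were compared with random pairs. They were 0.72 percentage points less frequent, a value of -0.72 (95% interval -2.18 to 3.47). Median UMIs in the WT libraries were 8 or 9 for TRB and 5 for TRA, and 2.38% of random pairs lay under that ratio. Free RNA that left more UMIs would go uncounted, so this explanation stays open. Neither test covers 1 cell read under 2 unlike barcodes with similar UMI counts, so this was not tested. The number of animals per library and a difference between genotypes stay open as untested.

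The CD4-titled libraries, which were left out of the genotype comparison, shared 6829 barcodes. In 10 TRAV subgroups picked for a low match in 5xFAD, which leaves WT as the only informative side, 44.5%, 45.6% and 48.7% of dCLN, sCLN and iLN WT chains matched the reference, in V sequences that the planned usage test does not use.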

How the results depend on the processing

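The alternatives with non-reference TRA chains, TRA features alone, unpaired chains and the default DESeq2 trend were chosen after seeing the data. The genotype count of 2 features became 0 with UMIs counted, with DESeq2 under either dispersion trend, with at least 2 UMIs per chain, with the CD4-titled libraries added as a node level (the same cells under both labels), with all chains paired or not, and with non-reference TRA chains only, where TRAV4 went from -0.55 (standard error 0.16) to -0.14 (0.22) and TRAV3 from -0.86 (0.25) to -0.23 (0.34), so that the estimates shrank besides losing precision. It was 3 with cells counted and with TRA features alone (TRAJ21 added in each), 3 with a minimum of 1 clonotype (TRAJ35 added), 2 with ambiguous calls left out (TRAV4 and TRAV12), 1 with a minimum of 100 clonotypes and 24 with TRAV by gene, of which 5 were higher and 19 lower. Leaving out each library gave 0 to 0. TRAV4 kept a negative value in all 20 alternatives that gave it (-0.70 to -0.14), passing in 7 (adjusted p 0.015 to 0.99), and TRAV3 passed in 5 and ranged from -1.03 to 0.15, the last with ambiguous calls left out. TRBV17 turned to 0.0198 with UMIs. In the genotype comparison DESeq2 had 0 features at an unadjusted p under 0.05 with the mean trend and 3 with the default trend. Node contrasts gave 0 to 1 calls without each library for dCLN against sCLN (1 without sCLN WT) and 0 to 2 for sCLN against iLN (2 without iLN WT); 1 for dCLN against iLN with a minimum of 100 clonotypes, and 1 for sCLN against iLN with extra chains kept. Without each node type in turn, the mean genotype difference ran from -3.99 to 0.0456 percentage points for the SJL block, -1.15 to 0.49 for TRAV9, -0.287 to 0.0585 for hydrophobic TRB positions and -0.0191 to 0.0661 amino acids for TRB length; with TRB alone, 27 clonotypes were shared within and 21 between genotypes. Contigs of at least 2 UMIs lowered pairing to 53.4% in dCLN WT, 50.2% in sCLN WT, 64.8% in sCLN 5xFAD, 60.4% in iLN WT, 67.3% and 67.6% in the CD4-titled libraries and 68.1% in the mixed library, and by less, within the counting interval, to 56.9% in dCLN 5xFAD and 41.6% in iLN 5xFAD. Except where construction is named, the cause was not tested. The shares of cells in repeated clonotypes and of iNKT chains kept their direction in all alternatives run (-6.07 to -2.60 percentage points for repeated clonotypes without each node type). The list alternatives with nonproductive chains were not run, as the 6 main libraries list none, nor was the cell-based agreement of dCLN preparations, as the CD4-titled libraries are 1 sample.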

Other observations

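The tests of cells with 2 TRA chains, of the CD4-titled sample and of non-reference iNKT chains were chosen after the result was seen; the test of reference iNKT chains was fixed before its value was seen.

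In WT cells with 2 TRA chains, the chains were nearly always of different germline classes. Of 63 such cells in informative subgroups, 59 carried 1 reference and 1 other chain, or 93.7% (exact 95% interval 84.5 to 98.2), where independent draws would give 50%. A candidate explanation is that WT animals carried both TRA haplotypes, each chromosome giving 1 chain. An expectation written before the value was seen had named 50% for this explanation; it was wrong, because the chains of a cell come from different chromosomes, and the present form of the test was written afterwards.

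The TRA reference share of the CD4-titled sample, 35.0% of all TRA chains under the label WT, lay between those of dCLN WT and dCLN 5xFAD. In the library labelled WT, 48 of 108 cells with 2 informative TRA chains carried a chain of each class, 58 carried 2 other chains and 2 carried 2 reference chains. The share of 44.4% (exact 95% interval 34.9 to 54.3) lay below that of WT cells, which argues against animals of the WT type alone. The sample may be a pool of animals of the WT type and of the 5xFAD type, for which 48.5% would be awaited. Independent draws would give 36.6%, which also lies in the interval, so this stays open. If it is such a pool, its differences from dCLN WT and dCLN 5xFAD set a mixture of genotypes against each.

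The absence of iNKT chains in 5xFAD was set against germline. Of 16 WT contigs with the chain, 5 had a reference TRAV11 region, or 31.2% (exact 95% interval 11.0 to 58.7), against 54.7% of all WT TRA chains, too few to decide on enrichment. The other 11, or 68.8% (41.3 to 89.0), had a non-reference region, which argues against a germline of the 5xFAD libraries that cannot form the chain, if the non-reference chains of WT and 5xFAD share a haplotype. Other strain differences and the transgene stay open, untested.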
